A study of Drosophila melanogaster with 175 samples.

How the data were processed

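The labels describe 3 sequencing experiments on Drosophila melanogaster embryos, held here as 175 sequencing runs from 67 libraries in 19 groups. The Slbp experiment had 26 single embryos grown at 18 °C. Of these, 5 Slbp RNAi and 5 wild-type (WT) embryos preceded nuclear cycle 9 (pre-NC9), 5 Slbp and 6 WT embryos were at NC13, and 5 WT embryos were at NC14. The pooled abo experiment had 3 abo and 3 WT libraries of 40 embryos each at NC14. The abo time course had 35 single embryos, with 2 abo and 3 WT unfertilized eggs (NC0) and 3 embryos of each genotype at each of NC10, NC11, NC12, NC13 and NC14. Both abo experiments were grown at 25 °C. The labels name Slbp RNAi a histone knockdown and abo a histone overexpression. They give 5 Slbp NC13 embryos where the design text gives 4, and the labels were followed.

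Per the labels' protocols, embryos were staged and imaged at 22 °C. RNA of the Slbp embryos was depleted of ribosomal RNA and then converted to cDNA from an oligo-dT adaptor by Smart-seq2. The time course used oligo-dT Smart-seq2 alone, both with Nextera libraries, and the pools used oligo-dT beads with a PrepX kit and carried ERCC spike-ins. All 3 therefore measured polyadenylated RNA, as single-end reads of 75 nt on an Illumina HiSeq. Tools named per the submitters' processing notes are Trim Galore 0.5.0, Salmon 0.10.2 and DESeq2 1.20.0, without a role for each. Neither strandedness nor the annotation release behind the transcript index is given in the sources used here.

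The deposited Salmon tables gave expected counts per transcript and run, which were the values analysed here, and effective lengths of another kind of unit, bases, which served only for an offset. The authors' differential tables gave log2 fold changes and adjusted p-value columns, used only for comparison. The authors' normalized tables held signal values in 91 columns of per-sample values, which were not used for any test. Of 29760 transcripts in the index, 29542 were matched by name to 13624 genes of the BDGP6.54 annotation. The other 218 transcripts, with 0.124% to 0.273% of the reads of a library, were left out.

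Expected counts were summed over the transcripts of a gene and over the runs of an embryo, and were rounded. The 31 copies of the replication-dependent histone genes in the index (His1 12, His2A 4, His2B 7, His3 2, His4 6) were summed to 5 family features, since reads of 75 nt cannot be told apart among copies, which left 13598 features. Runs of 1 embryo were technical repeats, and their ranks correlated at 0.997 or more in the Slbp experiment (3 pairs) and 0.966 or more in the time course (210 pairs). All Slbp-experiment embryos had a run in Batch 2, and Slbp NC13 embryos 1 and 2 and WT NC13 embryo 1 also had a run in Batch 1. No pair of libraries was a duplicate.

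Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3. Features were filtered with filterByExpr, libraries were scaled by TMM (factors 0.664 to 1.12, 0.945 to 1.03 and 0.610 to 1.15), and a quasi-likelihood (QL) model with 1 mean per group was fitted. Every adjusted p-value of a gene in the text is from this test with Benjamini-Hochberg (BH) correction within a comparison, called under 0.05, and n is the number of embryos or pools. Features tested numbered 7590, 8957 and 7212. The standard errors beside log2 fold changes are approximate, from the absolute log2 fold change divided by the root of the F value. Levels are TMM-scaled CPM, mean ± SD. P-values and intervals for gene span, chromosome arms and preset-correlation camera treat genes as units, and others cover spread among libraries or counting error alone. A fold against a group without a read was computed against a floor of 3 reads over that group, and with 1 to 3 reads the ratio of scaled counts is given with its 95% counting interval.

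Gene lists were tested with camera and fry of limma 3.58.1 on voom values, camera with a preset correlation of 0.01 and again with an estimated correlation. BH correction ran over the lists of a comparison. The 21 lists written before the data were examined hold gap, pair-rule and terminal genes; dorsoventral patterning genes; earliest zygotic genes; cellularization genes; maternal RNAs cleared after egg activation; germ plasm RNAs; cell cycle regulators; DNA replication genes; histone families; histone variants; histone chaperones and stores; histone mRNA biogenesis; ribosomal protein genes; mitochondrial transcripts; DNA damage and apoptosis genes; heat shock genes; pioneer and early regulators; dosage compensation genes; and 3 lists of possible contaminants (eggshell and yolk, late embryonic differentiation, testis and sperm). Of testis and sperm genes 0 passed the edgeR filter in any experiment, so none was tested and 0 had an unadjusted p under 0.05. Of eggshell and yolk genes only 5 passed, in the pools.

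To measure developmental stage, a zygotic and a maternal-decay list were taken from the WT embryos of the other experiment, so that no library helped define the list it was scored with. The zygotic list required WT NC14 at least 4-fold above the earliest WT group and at most 1 CPM in the latter (330 genes from the time course, 579 from the Slbp experiment). The maternal-decay list required at least a 2-fold fall (1894 and 2471 genes). Of these, 295 and 1840 genes were shared by the 2 experiments. The stage score of a library is its mean log2(CPM + 1) over the zygotic list minus that over the maternal-decay list. Scores were compared by exact permutation of the group labels, or by 100000 resamples within stages for the time course as a whole.

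Genes named in the text were picked by a rule written before the data were examined. It always took Slbp, abo and the 5 histone families. For the 4 main comparisons it took called genes with a mean of at least 5 CPM and no overlap between groups (for the time course average, the same sign at 5 stages). Among these it kept the 6 largest rises and falls, the 4 largest among genes with a given name, and up to 2 members per list with the smallest adjusted p. For other comparisons it took the 3 largest each way. Of 3 against 3 libraries, 10% of genes separate by chance.

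The procedure was tested on simulated data with the group sizes and dispersions of each experiment. Libraries were drawn independently from a single base level per gene, and few genes were changed, all of them well covered by reads. The shares below need not hold where same-numbered embryos deviate together, as in the time course, or where most genes are called, as at NC13. It recovered 71% of genes changed 2-fold at pre-NC9, 70% at NC13 (9.44% of calls were false there), 39% in the pools, 49% at NC14 of the time course and 96% in its average. For 4-fold changes it recovered 94%, 93%, 83.8%, 94% and 100%. Tables of counts, the comparison with the authors' tables and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and DESeq2 1.42.0 served as the alternative test. Alternatives set beforehand were its size factors, upper-quartile scaling, no filter, single histone copies, a transcript length offset, the compared groups alone, the replicate number as a block, single batches, a stage score pseudocount of 0.1, and leaving out each library in turn. Alternatives added after results were seen were ERCC scaling of the pools, the legacy edgeR dispersion, reads summed by embryo number, and leaving out WT embryos 3 or Slbp NC13 embryos 3 and 4.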

Results

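To ask how polyadenylated RNA of early Drosophila embryos differs with histone supply, single Slbp RNAi embryos and single or pooled abo embryos were compared with WT embryos of the same stage label. The Slbp experiment held 26 embryos with a median of 8.49 (range 3.54 to 22.2) 1e6 reads each, the pooled abo experiment 6 libraries with 51.7 (29.6 to 65.9), and the abo time course 35 embryos with 4.57 (2.92 to 6.69). Genes with at least 1 read numbered 7215 to 11013, 8572 to 10226 and 7207 to 8105 per library. Genotype was the maternal treatment in each case, so a difference between groups covers the knockdown or mutation together with any difference in strain or parents, and growth temperature and library method differed between experiments.

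To see what Slbp RNAi changed before zygotic transcription, 5 Slbp embryos were compared with 5 WT embryos at pre-NC9. Slbp itself, which encodes the stem-loop binding protein of histone mRNA, lay at 2.23 to 4.26 CPM in every Slbp embryo against 221.5 to 281.2 CPM in every WT embryo. Its means were 3.14 ± 0.757 and 251 ± 23.3 CPM (log2 fold change -6.34 ± 0.31, edgeR QL with BH, adjusted p = 6.5e-14). Polyadenylated reads of the histone families moved in both directions. His3 rose (2.31 ± 0.30, edgeR adjusted p = 8.32e-06) and His2B rose (1.25 ± 0.27, adjusted p = 0.00283). The linker histone His1 fell (-2.44 ± 0.35, edgeR adjusted p = 2.26e-05), His2A fell (-1.23 ± 0.19, adjusted p = 7.41e-05) and His4 did not pass (-0.15 ± 0.21, adjusted p = 0.81). The small heat shock genes Hsp23 (5.70 ± 0.46, from 8.71 ± 2.56 to 452 ± 243 CPM, edgeR adjusted p = 2.15e-09) and Hsp22 (3.49 ± 0.54, adjusted p = 6.87e-05), which encode chaperones, rose in the Slbp embryos. Transcripts of PGRP-LC, an immune receptor of peptidoglycan, rose from 1 read to 1027 reads (ratio 967, counting interval 173 to 38210, edgeR adjusted p = 1.02e-04; at least 264-fold without WT embryo 5).

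The other large rises at pre-NC9 were CG13857, with no read in WT (at least 325-fold higher in Slbp, edgeR adjusted p = 6.66e-04; at least 205-fold without Slbp embryo 4), and CG32640 (ratio 768, counting interval 262.5 to 3727, adjusted p = 5.85e-09; at least 562-fold without WT embryo 3). Next came bark (ratio 305, counting interval 84.1 to 2523, edgeR adjusted p = 3.06e-08; at least 149-fold without WT embryo 3) and CG4115 (6.74 ± 0.82, adjusted p = 5.48e-07). The glutathione transferase GstD2 (7.10 ± 0.68, 6.31 without Slbp embryo 3, edgeR adjusted p = 5.69e-09) and the testis thioredoxin TrxT (6.71 ± 0.71, adjusted p = 1.1e-07) rose as well. The ribosomal protein paralog RpS19b, usually of the germline, rose by 5.98 ± 0.82 (edgeR adjusted p = 1.61e-06, 6.66 without WT embryo 5). Of cell cycle genes, Cdk4 rose (1.17 ± 0.26, edgeR adjusted p = 0.0044, 120 against 52.6 CPM). The mitotic kinase subunit Cks30A rose (0.53 ± 0.14, edgeR adjusted p = 0.0158) but lost its call without Slbp embryo 4, WT embryo 3 or WT embryo 4 (adjusted p = 0.0502, 0.0583 and 0.0574). The cyclin inhibitor rux fell (-0.76 ± 0.19, edgeR adjusted p = 0.00952, 0.051 without WT embryo 3). The receptor Ir76a (-3.08 ± 0.45, edgeR adjusted p = 1.46e-05), the transferase Ugt50B3 (-4.89 ± 0.78, -4.19 without WT embryo 3, adjusted p = 5.77e-05), CG31886 (-3.08 ± 0.63, adjusted p = 0.00155) and CG32243 (-2.79 ± 0.48, adjusted p = 2.98e-04) fell. The replication clamp PCNA fell (-0.45 ± 0.10, edgeR adjusted p = 0.003), a call lost under upper-quartile scaling (-0.36, adjusted p = 0.074), with a transcript length offset (-0.37, adjusted p = 0.0838) and with the 2 groups fitted alone (-0.37, adjusted p = 0.0583). RpL6 fell (-0.53 ± 0.11, edgeR adjusted p = 0.002) and abo did not pass (-0.22 ± 0.21, adjusted p = 0.683).

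Over all 7590 genes at pre-NC9, edgeR QL with BH called 504, of which 360 rose and 144 fell (295 and 48 by over 2-fold). With upper-quartile scaling 394 rose and 88 fell, and with Batch 2 runs alone 374 rose and 159 fell. Of 13 heat shock genes, 6 rose, 0 fell and 7 did not pass (7 passed when adjusted over the list alone), with a camera adjusted p = 5.89e-06 (adjusted p = 6.22e-04 with an estimated correlation). Of 86 ribosomal protein genes, 1 rose, 5 fell and 80 did not pass (15 adjusted over the list alone; median -0.24, camera adjusted p = 3.96e-09, adjusted p = 0.698 with an estimated correlation). Histone families as a list had a camera adjusted p of 0.45 (2 rose, 2 fell, 1 did not pass, 4 adjusted over the list alone). Of 30 cell cycle regulators 1 rose, 2 fell and 27 did not pass (3 adjusted over the list alone), and of 27 DNA replication genes PCNA alone passed. Of 9 histone mRNA biogenesis genes Slbp alone passed, and the maternal RNAs cleared after egg activation had 1 rise, Cks30A, among 18. In the 12 other lists together 0 of 154 genes passed in edgeR, 17 of them with an unadjusted p under 0.05. Zygotic genes, taken from the WT embryos of the time course, had 20 rises and 0 falls among 323 (18 adjusted over the list alone; camera adjusted p = 9.64e-05, adjusted p = 0.698 with an estimated correlation and 0.0861 under upper-quartile scaling). Maternal-decay genes from the same source had 46 rises and 23 falls among 1887 (49 adjusted over the list alone; camera adjusted p = 0.237, but 0.0271 on DESeq2 Wald statistics, 0.00851 with no filter, 0.0212 without Slbp embryo 5 and 6.7e-05 without WT embryo 1). At an equal depth of 3528790 reads the Slbp embryos had reads in 7961 genes and the WT embryos in 7236, the lowest Slbp embryo (7454) above the highest WT embryo (7314).

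To see what changed by NC13, 5 Slbp embryos were compared with 6 WT embryos. Slbp was still lower (39.0 ± 23.3 against 84.1 ± 17.2 CPM, log2 fold change -1.12 ± 0.22, edgeR QL with BH, adjusted p = 1.41e-04), at 26.07 to 31.9 CPM in 4 embryos and 80.4 CPM in embryo 4, against 58.6 to 101 CPM in WT. Polyadenylated histone reads rose steeply in Slbp embryos. His3 rose from 70.02 ± 10.7 to 11516 ± 3135 CPM (7.36 ± 0.34, edgeR adjusted p = 1.63e-14). So did His2B from 761 ± 103 to 37730.3 ± 14330.1 CPM (5.63 ± 0.29, edgeR adjusted p = 7.46e-14). His4 rose from 542 ± 71.2 to 12009 ± 2283 CPM (4.47 ± 0.23, edgeR adjusted p = 5.59e-14) and His2A from 2608 ± 258 to 11462 ± 3392 CPM (2.14 ± 0.18, adjusted p = 3.76e-10). His1 did not pass (0.55 ± 0.31, edgeR adjusted p = 0.123) but did under DESeq2 size factors (0.75, adjusted p = 0.044), with DESeq2 Wald tests (0.76, adjusted p = 0.0472) and with a transcript length offset (0.73, adjusted p = 0.0441). The 5 families together made up 7.36% of reads in Slbp embryos and 0.458% in WT. The pole plasm RNA osk, which anchors germ plasm assembly, fell (-4.05 ± 0.22, edgeR adjusted p = 1.5e-13), as did the mitotic phosphatase stg (-1.98 ± 0.14, adjusted p = 1.59e-11) and the checkpoint kinase grp, fly Chk1 (-1.71 ± 0.11, adjusted p = 3.5e-12).

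**Figure D1:**
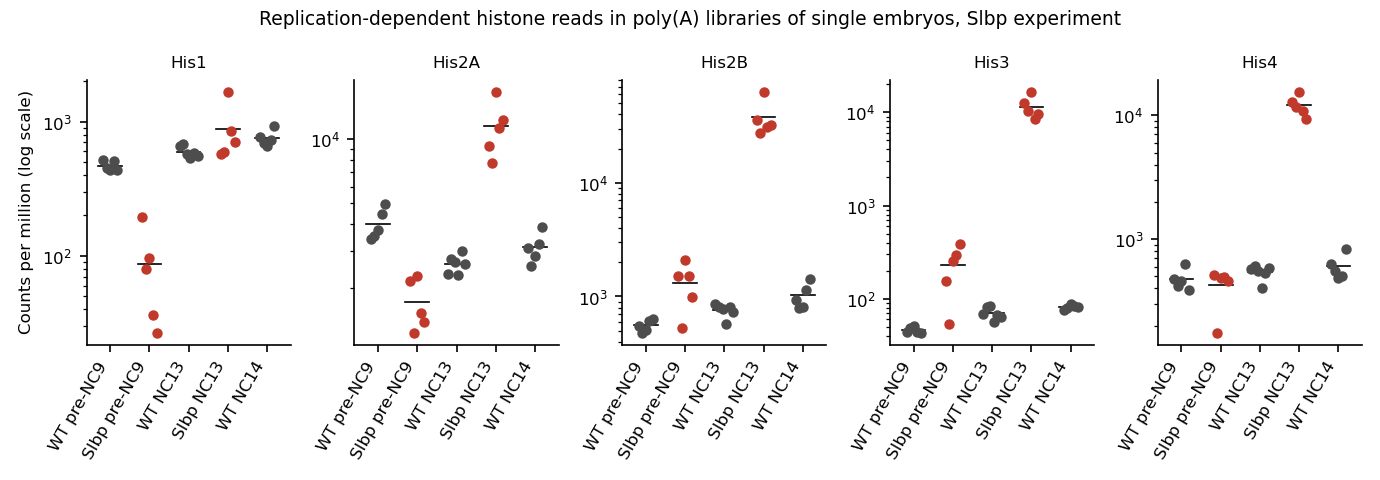
Reads of the 5 replication-dependent histone families in each library of the Slbp experiment, in CPM on a log scale, by stage and genotype. Values are sums over the copies of a family in polyadenylated RNA, and each point is 1 embryo.

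Of patterning genes of the blastoderm at NC13, 13 of 20 gap, pair-rule and terminal genes and 14 of 20 dorsoventral genes rose and 0 and 1 fell, but neither list passed with an estimated correlation (adjusted p = 0.178 each). The pair-rule gene opa rose by 6.43 ± 0.76 (edgeR adjusted p = 8.14e-09), 4.43 without Slbp embryo 4, and hairy (hry) rose by 2.06 ± 0.24 (adjusted p = 6.56e-09). The dorsoventral genes sog, a BMP inhibitor (2.02 ± 0.23, edgeR adjusted p = 3.12e-09), and brk, a repressor of BMP targets (2.11 ± 0.25, adjusted p = 8.24e-08), rose, as did the GATA factor srp (3.44 ± 0.53, 2.31 without Slbp embryo 4, adjusted p = 2.7e-06). The neural genes elav (4.25 ± 0.58, edgeR adjusted p = 4.58e-07), dan (7.51 ± 0.93, adjusted p = 1.63e-08) and danr (5.98 ± 0.87, adjusted p = 6.4e-07) rose, dan to 4.71 and danr to 3.32 without Slbp embryo 4. CG7191 rose by 7.68 ± 1.07 (edgeR adjusted p = 3.13e-07; 6.38 without Slbp embryo 4, and a ratio of 304, counting interval 103.7 to 1476, without WT embryo 1), and CG32640 was high again (ratio 1354, counting interval 463 to 6566, adjusted p = 4.12e-11; at least 1120-fold without WT embryo 2). The pro-apoptotic gene rpr (3.42 ± 0.39, edgeR adjusted p = 3.21e-08), Hsp23 (4.34 ± 0.39, adjusted p = 7.16e-10) and the mitosis inhibitor Z600, known as fruhstart (1.78 ± 0.29, adjusted p = 2.37e-06), rose. Smaller rises were sisA, an X-linked counting gene (1.48 ± 0.33, edgeR adjusted p = 3.41e-04, but 0.052 with DESeq2), grh (1.12 ± 0.27, adjusted p = 8.21e-04) and the male dosage compensation gene msl-2 (0.93 ± 0.21, adjusted p = 4.33e-04). The histone variant gene His3.3B (0.67 ± 0.18, edgeR adjusted p = 0.0026) and the myosin gene zip (0.54 ± 0.16, adjusted p = 0.00528) rose. RpL7-like rose (0.51 ± 0.11, edgeR adjusted p = 4.03e-04), as did RpS15Ab (1.16 ± 0.23, adjusted p = 9.79e-05), whose near-identical paralog makes its count uncertain. The mitochondrial transcripts mt:ND4 (2.02 ± 0.47, edgeR adjusted p = 7.68e-04, but 0.99 without Slbp embryo 3) and mt:ND6 (1.67 ± 0.39, adjusted p = 6.83e-04) rose too.

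Of the 2187 falls at NC13, 1009 were of maternal-decay genes, of which 243 rose. Besides osk, the translational repressor bru1 (-3.54 ± 0.22, edgeR adjusted p = 1.35e-12), the Polo inhibitor mtrm (-3.70 ± 0.25, adjusted p = 6.19e-12) and the dorsoventral factor dl, Dorsal (-3.24 ± 0.33, adjusted p = 5.27e-09), fell. So did Ir76a (-4.82 ± 0.49, edgeR adjusted p = 1.25e-09), Mctp (-4.64 ± 0.38, adjusted p = 1.51e-10) and CG12024 (-4.57 ± 0.26, adjusted p = 1.73e-14). CG13850 (-4.36 ± 0.31, edgeR adjusted p = 6.18e-12), CG4991 (-4.18 ± 0.31, adjusted p = 2.49e-11) and olf186-M (-4.16 ± 0.28, adjusted p = 5.31e-12) fell. Of 15 histone chaperones and stores 6 fell and 3 rose, and the falls include Jabba, the lipid droplet anchor of histones (-3.72 ± 0.20, edgeR adjusted p = 1.5e-13), and the H3.3 chaperone Hira (-2.52 ± 0.21, adjusted p = 3.1e-10). The histone locus body scaffold mxc fell (-1.43 ± 0.24, edgeR adjusted p = 1.54e-05), and of 6 histone variants 4 rose and BigH1, the embryonic linker histone, fell (-1.25 ± 0.32, adjusted p = 0.00173). Of replication and checkpoint genes, Orc1 (-1.74 ± 0.18, edgeR adjusted p = 1.16e-08), RnrL (-1.20 ± 0.14, adjusted p = 3.8e-08) and mus304, fly ATRIP (-1.58 ± 0.19, adjusted p = 1.3e-07), fell. DnaJ-1 (-2.58 ± 0.19, edgeR adjusted p = 2.69e-11), msl-3 (-0.80 ± 0.17, adjusted p = 3.1e-04), abo (-1.28 ± 0.22, adjusted p = 2.6e-05) and the early zygotic gene amos (-1.72 ± 0.35, adjusted p = 9.38e-05, but 0.0638 with DESeq2) also fell.

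Over all genes at NC13, edgeR QL with BH called 4539 of 7590, of which 2352 rose and 2187 fell (1176 and 1326 by over 2-fold). With Batch 2 runs alone 2352 rose and 2155 fell, and with the 2 groups fitted alone 1583 rose and 1815 fell. The median log2 of all genes was 0.0949 under TMM and 0.251 under DESeq2 size factors, with which 3045 rose and 1916 fell. Of 20 gap, pair-rule and terminal genes 13 rose, 0 fell and 7 did not pass (13 adjusted over the list alone). Camera gave 0.00248 as adjusted p (adjusted p = 0.178 with an estimated correlation). Of 20 dorsoventral genes 14 rose, 1 fell and 5 did not pass (15 alone; median 1.70, and 0.89 without Slbp embryo 4). Camera gave 0.00329 as adjusted p (adjusted p = 0.178 with an estimated correlation). Earliest zygotic genes were split (4 rose, 4 fell, 9 did not pass, 8 alone; camera adjusted p = 0.936), and of 15 cellularization genes 3 rose, 1 fell and 11 did not pass (3 alone; camera adjusted p = 0.249, but 0.0223 without Slbp embryos 3 and 4). Maternal RNAs cleared after egg activation fell (0 rose, 13 fell, 5 did not pass, 13 alone). Camera gave 8.52e-05 as adjusted p (adjusted p = 0.0477 with an estimated correlation). Germ plasm RNAs fell too (1 rose, 10 fell, 1 did not pass, 12 alone). Camera gave 2.07e-04 as adjusted p (adjusted p = 0.0477 with an estimated correlation). Cell cycle regulators had 6 rises, 14 falls and 10 that did not pass (20 alone). Camera gave 0.0155 as adjusted p (adjusted p = 0.178 with an estimated correlation). DNA replication genes had 1 rise, 13 falls and 13 that did not pass (14 alone; camera adjusted p = 0.0215, but 0.0546 without Slbp embryo 3 and 0.277 with an estimated correlation). Histone families had 4 rises and 0 falls (4 alone). Camera gave 2.18e-06 as adjusted p (adjusted p = 0.0477 with an estimated correlation). Histone variants had 4 rises and 1 fall among 6 (6 alone). Chaperones and stores had 3 rises and 6 falls among 15 (9 alone), and histone mRNA biogenesis 0 rises and 4 falls among 9 (4 alone).

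Among the remaining lists at NC13, all 13 mitochondrial transcripts rose (13 alone; median 1.43, and 0.91 without Slbp embryo 3). Camera gave 0.00273 as adjusted p (adjusted p = 0.497 with an estimated correlation). In addition 28 of 86 ribosomal protein genes rose and 0 fell (22 alone; median 0.23, camera adjusted p = 0.00329, adjusted p = 0.626 with an estimated correlation, and 0.286 without a filter). Heat shock genes split into 8 rises and 4 falls among 13 (13 alone; camera adjusted p = 0.905). Also split were DNA damage and apoptosis genes into 6 rises and 4 falls among 15 (10 alone), and pioneer and early regulators into 2 rises and 3 falls among 9 (5 alone). Dosage compensation genes had 2 rises and 2 falls among 6 (4 alone). Of 6 late differentiation genes 5 rose and 0 fell (5 alone; camera adjusted p = 0.03, but 0.0833 without Slbp embryo 3 and 0.203 with an estimated correlation). Of 323 zygotic genes taken from the time course WT, 222 rose, 10 fell and 91 did not pass (237 alone). Camera gave 1.4e-15 as adjusted p (adjusted p = 0.0546 with an estimated correlation). Of 1887 maternal-decay genes from the same source 243 rose, 1009 fell and 635 did not pass (1267 alone; median -0.80, camera adjusted p = 9.19e-18, adjusted p = 0.178 with an estimated correlation).

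To test directly whether the Slbp effect differed between the stages, the effect at NC13 minus that at pre-NC9 was fitted. With edgeR QL and BH it called 2429 genes, 870 with a higher and 1559 with a lower signed log2 effect at NC13 (1426 and 1416 with DESeq2 size factors, where the median of all genes moved from 0.0568 to 0.187). A lower signed effect can be a deeper fall or a smaller rise at NC13, so these counts do not say whether effects grew or shrank. The depletion of Slbp was smaller at NC13 by 5.23 ± 0.38 (edgeR adjusted p = 1.89e-10). All 5 histone families had a higher effect at NC13: His3 5.05 ± 0.42, His4 4.62 ± 0.31, His2B 4.38 ± 0.38, His2A 3.36 ± 0.27 and His1 2.99 ± 0.46 (edgeR adjusted p at most 1.32e-05). That of abo was lower (-1.06 ± 0.30, edgeR adjusted p = 0.00918). Germ plasm RNAs had lower signed effects at NC13 (0 higher, 9 lower among 12, 10 alone). Camera gave 1.95e-05 as adjusted p (adjusted p = 0.0121 with an estimated correlation). Lower as well were cleared maternal RNAs (0 higher, 10 lower among 18, 10 alone; camera adjusted p = 6.97e-05, adjusted p = 0.0465 with an estimated correlation). Of zygotic genes of the time course WT, 6 had a higher and 8 a lower signed effect (4 alone). Camera gave 0.00281 as adjusted p (adjusted p = 0.464 with an estimated correlation). Of maternal-decay genes 157 had a higher and 821 a lower signed effect (1072 alone). Camera gave 2.66e-18 as adjusted p (adjusted p = 0.222 with an estimated correlation).

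To set these changes against normal development, WT embryos of the Slbp experiment were compared with each other. From pre-NC9 to NC13, Slbp fell (-1.58 ± 0.21, edgeR QL with BH, adjusted p = 2.63e-07) and abo fell (-1.19 ± 0.20, adjusted p = 1.47e-05). Of histone families His2A alone passed (-0.63 ± 0.18, edgeR adjusted p = 0.00441), with His3 at 0.60 ± 0.29 (adjusted p = 0.0806, but 0.0437 under upper-quartile scaling). With the 2 groups fitted alone His3 (0.64, edgeR adjusted p = 3.68e-04), His2B (0.49, adjusted p = 0.00163) and His1 (0.38, adjusted p = 0.00179) passed too, as rises. CG10479 (at least 309-fold, edgeR adjusted p = 2.21e-10), kmr (at least 287.5-fold, adjusted p = 8.2e-09) and the insulator gene Elba3 (10.21 ± 0.41, adjusted p = 5.79e-22) rose, among 1891 rises (2720 with the 2 groups fitted alone). CG15047 (-8.45 ± 0.47, edgeR adjusted p = 1.01e-17), Cyp6a19 (-8.11 ± 0.38, adjusted p = 2.45e-17) and the helicase gene Fancm (-6.77 ± 0.55, adjusted p = 3.65e-12) fell, among 2383 falls (2512 with the 2 groups fitted alone). From NC13 to NC14, abo fell further (-0.95 ± 0.23, edgeR adjusted p = 0.00185), Slbp did not pass (0.13 ± 0.22, adjusted p = 0.647) and no histone family passed (His2B 0.43 ± 0.25, adjusted p = 0.168). With the 2 groups fitted alone, however, 4 of them did, His2B (0.48, edgeR adjusted p = 0.00938), His1 (0.39, adjusted p = 0.00422), His2A (0.32, adjusted p = 0.0182) and His3 (0.28, adjusted p = 0.0461). The POU factor nub (4.87 ± 0.76, 5.62 without WT NC13 embryo 1, edgeR adjusted p = 2.65e-05), opa (4.15 ± 0.91, adjusted p = 3.67e-04) and Atx-1 (3.50 ± 0.50, adjusted p = 1.05e-06) rose. CG3548 (-4.65 ± 0.63, edgeR adjusted p = 3.5e-07), Rab9 (-4.61 ± 0.58, adjusted p = 8.87e-08) and nebu (-4.22 ± 0.54, adjusted p = 2.06e-07) fell. In all 1153 genes rose and 1988 fell (721 and 2053 under upper-quartile scaling), but with the 2 groups fitted alone 2388 rose and 2202 fell.

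To place the Slbp embryos in developmental time, each library was scored by zygotic minus maternal-decay genes, from the time course WT. At NC13 the score was 1.22 ± 0.133 in 5 Slbp embryos and -0.728 ± 0.3995 in 6 WT embryos, a difference of 1.95 (exact p = 0.00216, the smallest that 462 splits can give; 1.94 with Batch 2 runs alone). WT NC14 embryos scored 1.25 ± 0.140, which Slbp NC13 embryos did not differ from by the test (-0.0252, exact p = 0.722). At pre-NC9 the difference was 0.334 (-5.68 ± 0.258 against -6.01 ± 0.222, exact p = 0.0635), and it passed without Slbp embryo 5 (exact p = 0.0397) or WT embryo 1 (exact p = 0.0238). Across genes the Slbp effect at NC13 correlated with the WT change from NC13 to NC14 of the time course (Pearson 0.404, Spearman 0.388), and of 607 genes called in both 590 had the same sign (516 fell in both against 197 by chance, 74 rose against 29.9). That correlation was 0.0861 without the zygotic and maternal-decay lists, and at pre-NC9 it was 0.118. It is 1 of 13 correlations computed, and genes are not independent replicates.

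**Figure D2:**
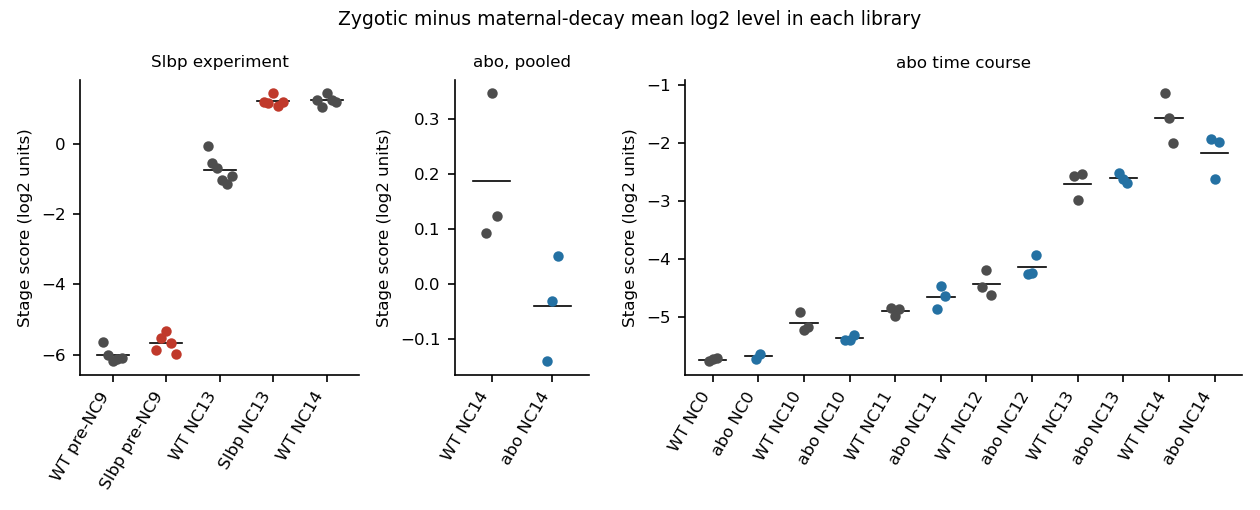
Stage score of each library (zygotic minus maternal-decay genes, lists from WT embryos of the other experiment) by experiment, stage and genotype.

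To find what set Slbp NC13 embryos apart from WT embryos with the same score, they were compared with 5 WT NC14 embryos. Slbp was lower (-1.24 ± 0.23, edgeR QL with BH, adjusted p = 6.83e-04). Histone reads stayed higher (His3 7.13 ± 0.36, His2B 5.20 ± 0.31, His4 4.32 ± 0.24, His2A 1.88 ± 0.19, edgeR adjusted p at most 1.73e-07), except His1 (0.22 ± 0.32, adjusted p = 0.672). The abo gene did not pass (-0.33 ± 0.25, edgeR adjusted p = 0.371). CG32640 (at least 667-fold higher, edgeR adjusted p = 9.03e-09) and narya (5.93 ± 0.37, adjusted p = 1.9e-12), a gene of meiotic crossing over, were higher. The kinase gene IP3K1 (-2.26 ± 0.37, edgeR adjusted p = 1.59e-04), the protease gene Sp7 (-2.27 ± 0.38, adjusted p = 2.12e-04) and Ugt50B3 (-2.73 ± 0.50, -3.38 without Slbp embryo 4, adjusted p = 3.72e-04) were lower. In all 1387 of 7590 genes passed in edgeR, 887 higher and 500 lower (1096 and 379 with DESeq2 size factors, where the median of all genes moved from 0.0713 to 0.181). With the 2 groups fitted alone 354 passed (243 higher, 111 lower), and with DESeq2 Wald tests 2147 (1682 higher, 465 lower). Heat shock genes were higher (6 higher, 0 lower, 7 not passed, 8 alone; median 2.83, camera adjusted p = 0.00529, adjusted p = 0.0349 with an estimated correlation). Cellularization genes, which build the membranes of NC14, were lower (0 higher, 3 lower, 12 not passed, 3 alone; median -0.28, camera adjusted p = 5.06e-04, adjusted p = 0.0447 with an estimated correlation). DNA damage and apoptosis genes had 6 higher and 1 lower (7 alone; camera adjusted p = 0.125).

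To see what loss of abo changed at NC14, 3 abo pools were compared with 3 WT pools of 40 embryos. The abo gene, named as a repressor of histone genes, was at 2.70, 0.524 and 0.582 CPM in abo and 4.75, 4.92 and 5.20 CPM in WT (log2 fold change -2.26 ± 0.54, edgeR QL with BH, adjusted p = 0.0196). That call was lost without abo pool 2 or 3 (-1.85, adjusted p = 0.141; -1.93, adjusted p = 0.0846) or WT pool 2 or 3 (adjusted p = 0.0572 and 0.0529), with the pool number as a block (adjusted p = 0.0713) and with legacy dispersions (adjusted p = 0.0991), and the value was -3.15 without abo pool 1. Polyadenylated histone reads were lower, not higher, in abo pools. His2B fell (-1.44 ± 0.16, edgeR adjusted p = 8.7e-05) and His4 fell (-1.04 ± 0.15, adjusted p = 6.66e-04). His1 fell (-0.90 ± 0.14, edgeR adjusted p = 0.00115) and His2A fell (-0.79 ± 0.16, adjusted p = 0.00692). His3 did not pass (-0.75 ± 0.23, edgeR adjusted p = 0.0633) but did without abo pool 1 (-1.03, adjusted p = 0.0171) or WT pool 1 (-0.87, adjusted p = 0.0467), by DESeq2 Wald test (-0.73, adjusted p = 0.0289) and with no filter (-0.75, edgeR adjusted p = 0.0453). Of 15 heat shock genes 11 rose, though the list did not pass with an estimated correlation (adjusted p = 0.256). Among them were Hsp23 (2.61 ± 0.25, edgeR adjusted p = 3.17e-05) and Hsp70Ab, whose copies are near-identical (3.09 ± 0.20, adjusted p = 1.58e-06). The replication genes Orc1 (-1.61 ± 0.15, edgeR adjusted p = 3.09e-05) and Mcm10 (-1.77 ± 0.18, adjusted p = 6.63e-05) fell.

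The largest rises in abo pools were Cyp12d1-d (at least 1264-fold, edgeR adjusted p = 2.96e-05) and Sdic3 (at least 1024-fold, adjusted p = 2.52e-05), both with near-identical paralogs. Without WT pool 1 the bounds were 685 and 555, and without WT pool 2 839 and 680. Ada1-1 (6.89 ± 0.43, edgeR adjusted p = 2.29e-07) and CG10962 (6.70 ± 0.62, adjusted p = 7.51e-06; at least 324-fold without WT pool 1, which held all 17 WT reads, and 6.11 without WT pool 2) followed. So did CG6567 (6.35 ± 0.31, edgeR adjusted p = 2.12e-07; 7.41 without WT pool 1), CG11164 (5.71 ± 0.28, adjusted p = 2.12e-07; 6.49 without WT pool 1) and hng3 (4.95 ± 0.32, adjusted p = 1.58e-06). The histone pre-mRNA processing gene Lsm11 (2.88 ± 0.28, edgeR adjusted p = 4.08e-05) and the maternal RNA regulator tral (1.53 ± 0.13, adjusted p = 1.12e-05) rose. The mitotic kinase aurA (1.38 ± 0.25, edgeR adjusted p = 0.00412), RpS5b (1.13 ± 0.11, adjusted p = 3.75e-05) and the FACT subunit dre4, fly Spt16 (1.13 ± 0.24, adjusted p = 0.0119, but 0.0702 without abo pool 2), rose. The falls included Dpm3 (-6.10 ± 0.34, edgeR adjusted p = 4.56e-07; -6.77 without abo pool 2) and TpnC4 (-5.52 ± 0.76, adjusted p = 2.13e-04; -7.49 without abo pool 3). The receptor gene clumsy (-5.35 ± 0.42, edgeR adjusted p = 5.63e-06; -6.54 without abo pool 2), Oseg5 (-5.21 ± 0.57, adjusted p = 3.95e-05) and CG42598 (-5.01 ± 0.49, adjusted p = 2.12e-05) fell too, and so did Polr3A, an RNA polymerase III subunit (-3.99 ± 0.32, adjusted p = 7.51e-06; -4.62 without abo pool 2). Of patterning genes Doc1 (-1.62 ± 0.28, edgeR adjusted p = 0.00257), tld (-0.91 ± 0.17, adjusted p = 0.00415) and hkb (-0.90 ± 0.18, adjusted p = 0.00789, but 0.0619 without abo pool 2) fell. The kinase Cdk5 (-1.43 ± 0.25, edgeR adjusted p = 0.00302) and the TNF ligand egr (-1.37 ± 0.16, adjusted p = 1.23e-04) fell as well. Slbp did not pass (-0.46 ± 0.16, edgeR adjusted p = 0.0979).

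Weaker calls in the pools depended on single libraries. The mitotic phosphatase stg rose (1.04 ± 0.24, edgeR adjusted p = 0.0165), but not without abo pool 1 or 2 or WT pool 2 or 3 (adjusted p = 0.0654, 0.1, 0.0896 and 0.0722). The gap gene tll fell (-0.86 ± 0.20, edgeR adjusted p = 0.0193), but not without the same pools (adjusted p = 0.0731, 0.101, 0.0888 and 0.0875). The NADH dehydrogenase transcript mt:ND2 fell (-1.02 ± 0.21, edgeR adjusted p = 0.00988), but not without abo pool 2 or WT pool 3 (adjusted p = 0.0658 and 0.0502) or with the pool number as a block (adjusted p = 0.0526). In all 814 of 8957 genes passed in edgeR QL with BH, 408 higher and 406 lower (257 and 219 by over 2-fold), with 500, 361 and 524 without abo pool 1, abo pool 2 and WT pool 3. Scaled by the ERCC spike-ins instead, the median of all genes moved from 0.0352 to -0.425 and edgeR called 0 genes (39 at an unadjusted p under 0.05), with His2B at -1.97 and Dpm3 at -6.51. By camera the histone family (adjusted p = 0.0026), dorsoventral (2.94e-04), gap, pair-rule and terminal (0.0026) and earliest zygotic (0.0441) lists still passed, and the eggshell and yolk list (4.2e-04) passed as well. The ERCC share ran from 0.119% to 1.57% among WT pools. Of 15 heat shock genes 11 rose, 0 fell and 4 did not pass (11 alone; median 1.77, camera adjusted p = 2.46e-11, adjusted p = 0.256 with an estimated correlation). Of 21 gap, pair-rule and terminal genes 0 rose, 6 fell and 15 did not pass (9 alone). Camera gave 5.12e-04 as adjusted p (0.644 with an estimated correlation). Of 21 dorsoventral genes 0 rose, 5 fell and 16 did not pass (7 alone). Camera gave 1.19e-05 as adjusted p (0.355 with an estimated correlation). Histone families had 0 rises and 4 falls (5 alone; median -0.90, camera adjusted p = 4.99e-07, adjusted p = 0.256 with an estimated correlation). Ribosomal protein genes had 9 rises and 0 falls among 87 (9 alone; median 0.21, camera adjusted p = 1.1e-06, adjusted p = 0.748 with an estimated correlation), a median of -0.64 under ERCC scaling.

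Of the other lists in the pools, cleared maternal RNAs had 3 rises and 0 falls among 18 (3 alone). Camera gave 0.0105 as adjusted p (0.256 with an estimated correlation). Earliest zygotic genes had 0 rises and 1 fall among 17 (1 alone; camera adjusted p = 0.0229, but 0.0876 without abo pool 3, 0.211 without WT pool 2, 0.112 without WT pool 3 and 0.748 with an estimated correlation). Cellularization genes had 0 rises and 1 fall among 15 (0 alone in edgeR; camera adjusted p = 0.0229, but 0.205 without WT pool 2 and 0.548 with an estimated correlation). Cell cycle regulators had 3 rises and 5 falls among 30 (17 alone) and DNA replication genes 1 and 3 among 27 (4 alone). Next were germ plasm RNAs with 2 and 2 among 14 (4 alone), histone chaperones and stores with 1 and 0 among 15 (2 alone), and histone mRNA biogenesis with 1 and 1 among 9 (4 alone). Mitochondrial transcripts had 0 rises and 1 fall among 13 (1 alone), DNA damage and apoptosis genes 0 and 2 among 15 (3 alone), and eggshell and yolk genes 1 and 0 among 5 (1 alone). In the 4 remaining lists tested 0 of 34 genes passed in edgeR, 8 of them with an unadjusted p under 0.05. Zygotic genes of the Slbp-experiment WT had 15 rises and 64 falls among 564 (91 alone; camera adjusted p = 0.0112, but 0.0983 without abo pool 1 and 0.748 with an estimated correlation). Maternal-decay genes had 135 rises and 54 falls among 2420 (174 alone; camera adjusted p = 0.0203, but 0.199 without abo pool 3, 0.956 without WT pool 2 and 0.873 with an estimated correlation). The stage score was -0.0404 ± 0.0962 in abo and 0.188 ± 0.139 in WT (difference -0.228, exact p = 0.1, the smallest that 20 splits can give).

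**Figure D3:**
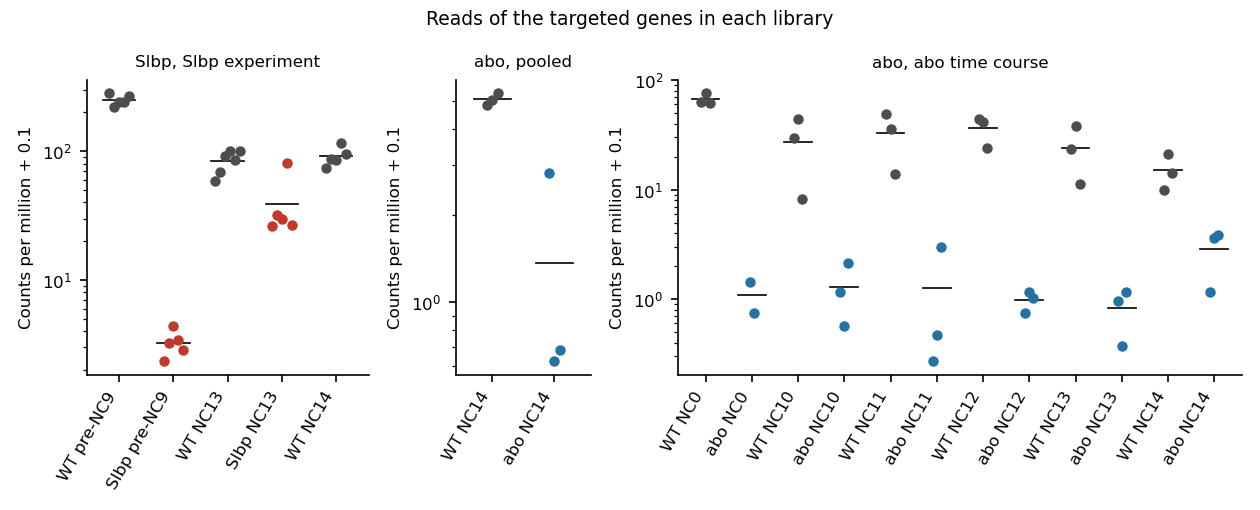
Slbp in each library of the Slbp experiment, and abo in each library of the pooled and time course abo experiments, by stage and genotype. Values are CPM with a small constant added, on a log scale.

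To follow the abo effect through the syncytial cycles, single abo and WT embryos were compared at each stage. The abo gene was lower in abo embryos at NC0 (-5.98 ± 0.73, edgeR QL with BH, adjusted p = 1.71e-06; without abo egg 1 a ratio of 103.4, counting interval 35.31 to 502) and NC10 (-4.64 ± 0.62, adjusted p = 7.82e-06). It was also lower at NC11 (-4.97 ± 0.64, edgeR adjusted p = 4.09e-06; without abo embryo 3 a ratio of 128, counting interval 43.6 to 624), NC12 (-5.33 ± 0.66, adjusted p = 1.92e-06) and NC13 (-5.07 ± 0.78, adjusted p = 6.76e-05). At NC14 it was lower by less (-2.49 ± 0.61, edgeR adjusted p = 0.0144), a call lost without abo embryo 1 (-2.08, adjusted p = 0.0881) or WT embryo 2 (-2.15, adjusted p = 0.0827) and with the 2 groups fitted alone (-2.50, adjusted p = 0.0516). Histone families passed at 2 stages alone. At NC0 His3 rose (2.15 ± 0.54, edgeR adjusted p = 0.0491), but not without abo egg 2 (0.39) or without WT egg 1, 2 or 3 (adjusted p = 0.0712, 0.264 and 0.135). Nor did it with the 2 groups fitted alone, legacy dispersions, or Batch 1 or Batch 2 runs alone (edgeR adjusted p = 0.209, 0.0778, 0.0517 and 0.0582). At NC13 His2B fell (-2.15 ± 0.56, edgeR adjusted p = 0.0204), His4 fell (-1.58 ± 0.43, adjusted p = 0.0254) and His1 fell (-1.23 ± 0.36, adjusted p = 0.0355). In the same order, they did not pass without WT embryo 1 (-0.85, -0.9996 and -0.70) or without abo embryo 2 (adjusted p = 0.104, 0.0563 and 0.0868) or 3 (adjusted p = 0.0799, 0.0692 and 0.107), nor with the 2 groups fitted alone (adjusted p = 0.1745, 0.14 and 0.1765). His4 and His1 did not pass without abo embryo 1 (adjusted p = 0.0967 and 0.0945). At NC14 no family passed (His2B -1.05 ± 0.55, edgeR adjusted p = 0.327), except His4 with the 2 groups fitted alone (-0.9995, adjusted p = 0.0128).

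Few genes passed at single stages of the time course in edgeR QL with BH, 68 at NC0, 144 at NC10, 117 at NC11, 98 at NC12, 472 at NC13 and 352 at NC14, of 7212 tested. Left out 1 at a time, the libraries moved these counts to 36 and 26 (NC0, abo eggs 1 and 2), to 68, 60, 81 and 75 (NC10, abo embryos 1, 2 and 3 and WT embryo 1) and 59 and 70 (NC11, abo embryo 2 and WT embryo 2). At NC13 they moved to 305, 207, 270, 150 and 973 (abo embryos 1, 2 and 3 and WT embryos 1 and 2), and at NC14 to 211, 131 and 170 (abo embryos 1 and 2 and WT embryo 1). Batch 1 runs alone gave 47, 115, 94, 84, 422 and 285 genes and Batch 2 runs alone 48, 120, 100, 85, 400 and 261. Cyp12d1-d, an insecticide-linked cytochrome P450 with a near-identical paralog, had no WT read at any stage and was at least 180-fold (NC0), 89.6-fold (NC10), 126-fold (NC11), 130-fold (NC12), 59.2-fold (NC13) and 131-fold (NC14) higher in abo (edgeR adjusted p at most 1.19e-04). CG10962 was higher at NC11 by at least 141-fold (edgeR adjusted p = 1.88e-10), and CG3104 at NC12 by at least 60.5-fold (adjusted p = 1.27e-06). CG4267 was lower at NC10 (ratio 440, counting interval 150 to 2135, edgeR adjusted p = 4.86e-14), NC12 (ratio 957, counting interval 171 to 37830, adjusted p = 2.16e-13) and NC13 (ratio 222, counting interval 60.9 to 1837, adjusted p = 1.38e-10). At NC13 Ada1-1 was at least 124-fold higher (edgeR adjusted p = 1.93e-07), and SK, a potassium channel gene, at least 33.9-fold lower (adjusted p = 0.00314, but 0.0517 with the 2 groups fitted alone). At NC14 Tfb4, a TFIIH subunit gene, fell (-5.49 ± 0.42, edgeR adjusted p = 4.16e-10), and CG42565 was at least 46.0-fold higher (adjusted p = 0.00754). Bounds depend on the depth of the group without a read, and with 1 library left out the lowest for Cyp12d1-d were 114 (NC0, WT egg 2), 46.8 (NC10, WT embryo 2), 80.3 (NC11, WT embryo 1), 74.4 (NC12, WT embryo 2), 32.2 (NC13, WT embryo 2) and 82.0 (NC14, WT embryo 2). They were 90.0 for CG10962 (WT embryo 1), 34.7 for CG3104 (WT embryo 2), 67.5 for Ada1-1 (WT embryo 2), 19.7 for SK (abo embryo 1) and 28.8 for CG42565 (WT embryo 2). CG4267 had a ratio of 292 without abo embryo 1 and 825 without abo embryo 2 at NC10, and at NC12 a ratio of 603 without abo embryo 3 and a bound of 219 without abo embryo 1. At NC14, 6 of 19 gap, pair-rule and terminal genes fell and 0 rose (9 alone; median -1.12, camera adjusted p = 1.61e-07, adjusted p = 0.237 with an estimated correlation). Of zygotic genes of the Slbp-experiment WT, 1 rose and 36 fell there among 344 (54 alone). Camera gave 6.75e-10 as adjusted p (0.396 with an estimated correlation). Of maternal-decay genes 156 rose and 32 fell among 2459 (281 alone). Camera gave 1.92e-08 as adjusted p (0.237 with an estimated correlation). Earliest zygotic genes at NC10 had 0 rises and 2 falls among 17 (12 alone; median -1.88, camera adjusted p = 8.23e-06, adjusted p = 0.545 with an estimated correlation).

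To gain power, the abo effect was averaged over NC10 to NC14 (15 embryos of each genotype). The abo gene was lower (1.35 ± 1.16 against 27.2 ± 14.03 CPM, log2 fold change -4.50 ± 0.30, edgeR QL with BH, adjusted p = 1.91e-13). His2B (-1.20 ± 0.25, edgeR adjusted p = 6.82e-04), His4 (-1.02 ± 0.19, adjusted p = 2.13e-04), His1 (-0.63 ± 0.16, adjusted p = 0.00461) and His2A (-0.63 ± 0.17, adjusted p = 0.00842) fell, and His3 did not pass (-0.48 ± 0.23, adjusted p = 0.136). The cell cycle genes Cdk4 (0.65 ± 0.08, edgeR adjusted p = 5.33e-07) rose and Dp, the partner of E2F (-0.47 ± 0.07, adjusted p = 2.06e-05), fell. The chaperone genes Nap1 (0.82 ± 0.18, edgeR adjusted p = 0.00154) and Ssrp, the other FACT subunit (0.45 ± 0.09, adjusted p = 6.33e-04), rose. Embryos of 1 genotype that share a number in the labels were not independent across stages, however. Their deviations from the stage mean correlated at 0.327 in WT, against -0.157 between numbers (exact p = 7.7e-04, the smallest that 1296 relabelings can give), and at 0.0808 against -0.0404 in abo (exact p = 0.0015).

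With reads summed by embryo number, so that 3 sums faced 3, the average comparison called 187 genes in edgeR QL with BH (82 higher, 105 lower) in place of 1561 (779 higher, 782 lower). Of the 187 genes, 181 had passed in the same direction with single embryos. Of 38 named genes that had passed, 14 did so with the sums. They are abo (-4.49, edgeR adjusted p = 0.00239), His4 (-0.99, adjusted p = 0.0483), Cdk4 (0.65, adjusted p = 0.0113), Dp (-0.46, adjusted p = 0.0377) and CG10962 (7.69, adjusted p = 4.44e-06). The others are Ada1-1 (4.73, edgeR adjusted p = 4.13e-04), pst (4.91), Rdh1 (3.90), CG10013 (3.39), CG4267 (adjusted p = 5.4e-05), CG42598 (adjusted p = 0.00425), Cyp12d1-d (adjusted p = 3.55e-04), Eip63F-1 (adjusted p = 0.0232) and pyd3 (adjusted p = 0.0441). His2B (-1.13, adjusted p = 0.0708), His1 (-0.58, adjusted p = 0.0642), His2A (-0.58, adjusted p = 0.371), Nap1 (0.72, adjusted p = 0.133) and Ssrp (0.35, adjusted p = 0.304) did not pass with the sums. Histone families as a list passed both ways (0 higher, 4 lower, 1 not passed, 5 alone; median -0.63, camera adjusted p = 0.00896, and 0.0019 with the sums, but 0.98 with an estimated correlation). So did mitochondrial transcripts (0 higher, 5 lower, 8 not passed, 11 alone; median -0.74, camera adjusted p = 0.00896, and 0.00523 with the sums, but 0.98 with an estimated correlation). Without the 5 WT embryos numbered 3 neither list passed (camera adjusted p = 0.104 and 0.332), nor did His2A (-0.24, adjusted p = 0.122). The mitochondrial median was -0.46 without WT NC10 embryo 3.

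In the single-embryo test of the average, the largest rises were Cyp12d1-d (at least 540-fold, edgeR adjusted p = 4.75e-11), CG10962 (7.93 ± 0.32, 8.54 without WT NC10 embryo 2, adjusted p = 2.28e-20) and Ada1-1 (5.71 ± 0.30, adjusted p = 7.64e-15). The learning gene pst (5.04 ± 0.42, 5.98 without WT NC13 embryo 3, edgeR adjusted p = 1.78e-11), the dehydrogenase gene Rdh1 (3.95 ± 0.36, adjusted p = 4.9e-10) and CG10013 (3.62 ± 0.46, adjusted p = 2.27e-07; 4.55 without WT NC11 embryo 3 and 4.47 without WT NC14 embryo 2) followed. The largest falls were Eip63F-1 (at least 818-fold, edgeR adjusted p = 1.03e-04), Cyp4p2 (-9.22 ± 1.27, adjusted p = 5.31e-06), CG4267 (-7.32 ± 0.24, adjusted p = 7.28e-23), CG42598 (-7.10 ± 0.72, adjusted p = 1.04e-08) and pyd3 (-5.32 ± 0.82, adjusted p = 9.6e-06). Without the WT embryos numbered 3, CG42598 was -6.22 and pyd3 -3.88. Cyp4p2, near absent from WT embryos numbered 3, and GstE10 did not pass the filter with reads summed by number and so have no test there. GstE10 passed (ratio 290.5, counting interval 99.0 to 1412, edgeR adjusted p = 0.01) but exceeded 0.258 CPM in the WT embryos numbered 3 alone. It lost its call without any 1 of them (adjusted p = 0.5265 to 1). CG13532 (-5.91 ± 1.01, edgeR adjusted p = 2.35e-05) lost its call without WT NC12 embryo 1 (-5.03, adjusted p = 0.0812) and with reads summed by number (adjusted p = 0.0591). Its value was -4.73, -5.21 and -6.50 without WT NC10 embryo 1, WT NC14 embryo 2 and abo NC13 embryo 3. Hsp68 (1.46 ± 0.35, edgeR adjusted p = 0.00256), msl-2 (1.12 ± 0.24, adjusted p = 8.77e-04) and Irbp, fly Ku70 (0.63 ± 0.13, adjusted p = 6.13e-04), rose. So did mtrm (0.47 ± 0.12, edgeR adjusted p = 0.00358), bru1 (0.37 ± 0.11, adjusted p = 0.0186), Sry-beta (0.32 ± 0.08, adjusted p = 0.00429) and Mcm2 (0.29 ± 0.08, adjusted p = 0.0112). The piRNA gene aub (-0.40 ± 0.10, edgeR adjusted p = 0.00358) and the translational repressor pum (-0.37 ± 0.11, adjusted p = 0.0124) fell. So did RpL21 (-0.83 ± 0.18, edgeR adjusted p = 0.0014), RpS29 (-0.51 ± 0.15, adjusted p = 0.0124) and Hsp22 (-0.75 ± 0.20, adjusted p = 0.00782). None of these 12 genes, from Hsp68 on, passed with reads summed by number. Slbp did not pass (0.16 ± 0.12, edgeR adjusted p = 0.353).

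Over the lists of the average, cell cycle regulators had 4 rises and 4 falls among 30 (8 alone) and ribosomal protein genes 0 and 10 among 86 (1 alone). Histone chaperones and stores had 2 rises and 0 falls among 15 (2 alone), DNA replication genes 2 and 1 among 27 (1 alone), and histone mRNA biogenesis 0 and 2 among 9 (2 alone). Cellularization genes had 2 rises and 0 falls among 15 (1 alone), cleared maternal RNAs 1 and 1 among 18 (2 alone), and germ plasm RNAs 1 and 2 among 12 (3 alone). DNA damage and apoptosis genes had 1 rise and 1 fall among 14 (2 alone), heat shock genes 1 and 1 among 10 (3 alone), and dosage compensation genes 1 and 0 among 6 (1 alone). In the 6 other lists tested 0 of 70 genes passed in edgeR, 7 with an unadjusted p under 0.05. Zygotic genes of the Slbp-experiment WT had 22 rises and 18 falls among 344 (33 alone; camera adjusted p = 0.85) and maternal-decay genes 307 rises and 212 falls among 2459 (512 alone; camera adjusted p = 0.4661, but 0.00607 with no filter). Batch 1 runs alone gave 698 rises and 665 falls, and Batch 2 runs alone 711 and 643. The stage score difference did not pass over the stages (-0.0486, permutation p = 0.656) or at NC14 (-2.17 ± 0.376 in abo, -1.57 ± 0.427 in WT, exact p = 0.3). At NC0, NC10, NC11, NC12 and NC13 it was 0.0557, -0.260, 0.244, 0.289 and 0.0901 (exact p = 0.3, 0.1, 0.2, 0.3 and 0.8). The smallest p possible at each stage is 0.1, so none could pass, and at NC10 the groups did not overlap, with abo lower.

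**Figure D4:**
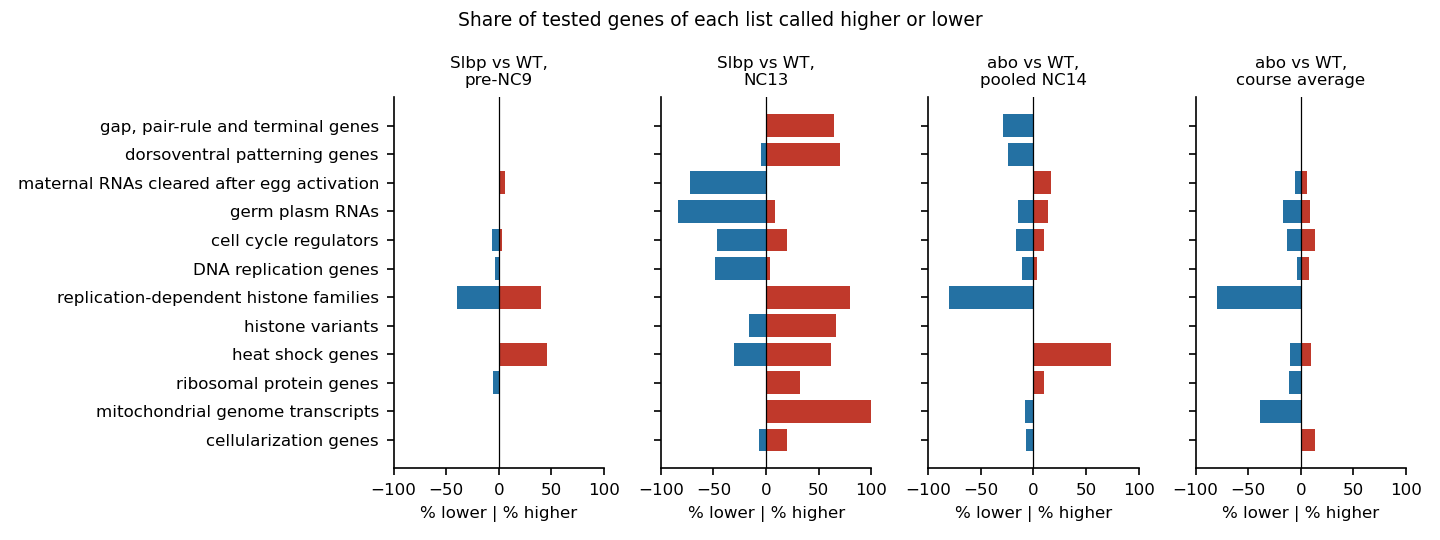
Share of tested genes of chosen lists called higher or lower (not medians) in Slbp and abo comparisons. Under ERCC scaling the medians of 8 of 22 lists in the pools turn from positive to negative. They are ribosomal protein, germ plasm, cleared maternal, maternal-decay, histone variant, chaperone and store, DNA damage and apoptosis, and pioneer genes.

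To ask whether the abo effect was the same in pools and single embryos, and whether it opposed that of Slbp RNAi, effects were correlated across genes. The pooled effect correlated with that of single embryos at NC14 (Pearson 0.437, Spearman 0.340; 112 of 114 genes called in both had the same sign). It also correlated with the average (Pearson 0.463, Spearman 0.283; 122 genes rose in both against 39.8 by chance and 139 fell against 40.9, of 276). The Slbp effect at NC13 correlated weakly with the pooled abo effect (-0.0837, Spearman -0.183), the abo effect at NC14 of the time course (-0.158, Spearman -0.278) and the abo average (0.0193, Spearman -0.0954), and the pre-NC9 Slbp effect at 0.0267, -0.0509 and 0.0529 in the same order. Of 471 genes called both at Slbp NC13 and in the pools, 331 had opposite signs (147 higher in Slbp and lower in abo against 118 by chance, 184 the reverse against 109). Of 229 called both at Slbp NC13 and in abo at NC14, 168 did (47 against 39.4 and 121 against 63.5), and of 896 shared with the average 496 did (238 against 215 and 258 against 231). With the WT change from NC13 to NC14 in the Slbp experiment, the abo effect correlated at -0.158 in pools, -0.266 at NC14 of the time course and -0.0599 in the average. The histone families His2A, His2B and His4 were higher under Slbp RNAi at NC13 and lower in abo pools (His2B 5.63 and -1.44). His1 did not pass at Slbp NC13 nor His3 in the pools, and at Slbp pre-NC9 His1 and His2A fell (-2.44 and -1.23), as they did in the pools. As a list the families passed at Slbp NC13 with an estimated correlation (adjusted p = 0.0477) but not in the pools (adjusted p = 0.256). Hsp23 was higher in Slbp embryos (5.70 at pre-NC9) and in abo pools (2.61). The heat shock list was less uniform, with 8 rises and 4 falls at Slbp NC13 (camera adjusted p = 0.905), 1 of each in the abo average, where Hsp22 fell (-0.75 ± 0.20, edgeR adjusted p = 0.00782), and no pass in the pools with an estimated correlation (adjusted p = 0.256).

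To relate these values to those of the submitters, the authors' differential tables were set beside the comparisons here. Their tables call 1214 genes at pre-NC9 and 4994 at NC13, with Spearman correlations of 0.929 and 0.957 to the log2 fold changes here and the same direction for at least 99.97% of genes called in both. The third Slbp column, named for NC14, was set beside Slbp NC13 against WT NC14 alone (1471 genes, Spearman 0.872, 895 shared calls). What it compares was assumed, and no other match was tried. For abo they call 1114 genes in the pools and 190, 191, 135, 143, 265 and 300 from NC0 to NC14. The best matches of their 4 normalized Slbp NC13 columns were embryos 1, 2, 3 and 5, so embryo 4, in which dan (4.71 without it) and opa (4.43 without it) were highest, has no column of its own there.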

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

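Single libraries were set against the others of their group with Dixon's ratio test, for read number, genes with a read, TMM factor, stage score and the CPM of Slbp, abo and each histone family, in every group of at least 4 libraries, and comparisons that tested a difference between stages were listed whenever genes passed. The test picks about 1 in 20 groups by chance, and it picked 6 of 55 here. No test of a cause was run for any of them.

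Slbp mRNA in Slbp NC13 embryo 4 was 80.41 CPM, against 26.07 to 31.9 CPM in the other 4, which puts this embryo within the WT range for the targeted gene. It also had the highest dan and opa, but its stage score and histone reads were not set apart by the test. Slbp NC13 embryo 3 had the most histone reads of its group, with His1 at 1663 CPM (others 576.3 to 852.6) and His2B at 62800 CPM (27180 to 35510). Without this embryo the Slbp effect on mt:ND4 was a log2 of 0.99. Slbp pre-NC9 embryo 2 had a low His4 of 175.7 CPM (460.1 to 515.7), and WT NC13 embryo 4 had a low His4 of 406 CPM (533.2 to 602.1). WT NC13 embryo 1 had 18.656 1e6 reads (5.231 to 10.182 in the others), and it is the WT NC13 embryo sequenced in 2 batches.

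The Slbp effect differed between pre-NC9 and NC13 for 2429 genes. Among them were Slbp itself, less depleted at NC13 by a log2 of 5.228 (edgeR adjusted p = 1.89e-10), and all 5 histone families, with differences of 5.047 for His3, 4.6221 for His4, 4.3831 for His2B, 3.3634 for His2A and 2.9936 for His1. For abo the difference was -1.0578 (edgeR adjusted p = 0.00918), and abo also fell with stage in WT embryos. The abo effect differed among the 5 stages from NC10 to NC14 for 30 genes.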

How the results depend on the processing

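The alternatives were chosen before the data were examined, except those named above as added after. Of named genes, 2928 alternative values kept call and direction or stayed uncalled, 107 lost the call, 14 gained one and 2 reversed. Over left-out libraries these were 3216, 123 and 3, without reversals. Of lists, 882 kept their call or stayed uncalled, 13 lost it, 11 gained one and 1 reversed (left-out libraries: 1186, 8, 8 and 1). Of gene counts 149 stayed within 1.5 times and 19 moved (left out: 154 and 21). The gene counts of the Slbp comparisons were the steadiest. Those that moved were Slbp NC13 against WT NC14, with 2147 genes by DESeq2 Wald tests and 354 with the 2 groups fitted alone, against 1387. In the pools the 814 genes became 522 with the pool number as a block and 0 under ERCC scaling, which lowered the median of all genes and where RpL19 (-0.537), CycB (-0.441) and the ribosomal list (-0.637) reversed, and the medians of cleared maternal RNAs (-0.303), maternal-decay genes (-0.297) and 5 lists without a call turned negative as well. The maternal-decay list of the pools had medians from 0.0132 without WT pool 2, where its test reversed, to 0.315 without WT pool 1. Time course counts fell with the compared groups fitted alone, to 37 (NC10), 43 (NC11), 54 (NC12), 56 (NC13), 86 (NC14) and 17 (differences between stages), and NC0 had 42 with legacy dispersions. Without the WT embryos numbered 3 counts rose to 255 (NC10), 155 (NC12), 1069 (NC13), 532 (NC14) and 93 (differences between stages), and DESeq2 gave 788 (NC13) and 93. The largest change for the abo average was 187 genes with reads summed by embryo number, against 1561. Leaving out 1 library moved counts between 361 and 800 in the pools, 26 and 56 (NC0), 60 and 158 (NC10), 59 and 96 (NC11), 150 and 973 (NC13), 131 and 367 (NC14), and 19 and 45 (differences between stages), the last from 30. The pre-NC9 stage score difference ran from 0.248 to 0.430, passing at 2 of the 10 omissions, and was 0.744 with a pseudocount of 0.1 (exact p = 0.0238). The labels do not say whether the numbers pair embryos of the 2 genotypes. Same-numbered embryos did not all correlate over 0.1 in any comparison, though at NC11 and NC13 of the time course 3 of 3 correlated best with their own number. With the number as a block, the NC13 score difference was 1.913 (exact p = 0.0625, the smallest possible), and the block gave 517, 4239, 2163, 4186, 2770 and 1610 genes in the Slbp experiment, 98, 209, 171, 138, 650 and 478 from NC0 to NC14, 1745 in the average and 30 between stages. Correlations moved too. At 5 CPM or more those with the WT change were 0.0166 (pre-NC9) and -0.284 (pools). Others were -0.225 (NC13 with pools) and 0.0267 (pre-NC9 with abo NC14). Without the zygotic and maternal-decay lists those with the WT change were -0.0465 (pre-NC9), 0.0861 (NC13) and -0.115 (abo NC14). The rest were -0.00809 (NC13 with pools, Spearman -0.126), -0.00431 (NC13 with abo NC14, Spearman -0.197) and 0.0761 (pre-NC9 with abo NC14). The cause was not tested for any of these.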

Other observations

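Beyond the comparisons above, the abo time course held genes whose difference between genotypes grew, shrank or changed sign with stage, listed after the values were seen. The difference of Tfb4, a TFIIH subunit gene, went from -0.40 at NC10 to -5.49 at NC14, that of Trs23 from -0.03 to -3.90, and that of Rpi from -0.35 to -3.27. In the other direction Nadk1b went from 0.61 to 3.47, CG4593 from 1.18 to 4.37, Arp10 from 0.47 to 3.48 and bsf from 0.69 to 3.57. The suppressor of cytokine signaling Socs44A started at -5.18 and ended at -1.0047. The head gap genes ems (-4.55) and oc (-3.20) were lower in abo at NC14, and mtrm was higher there (2.13).

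A second set of genes, also picked after the values were seen, followed the embryo number in the labels. GstE10 ran from 17.8 to 86.9 CPM in the 5 WT embryos numbered 3 and stayed at or below 0.258 CPM in all other embryos from NC10 to NC14. The cytochrome P450 gene Cyp4p2 ran from 60.2 to 135 CPM in WT embryos numbered 1 and from 23.3 to 84.8 CPM in those numbered 2, and stayed at or below 0.820 CPM in those numbered 3. Eip63F-1 had no read in any abo embryo, 52.6 to 111.5 CPM in WT embryos numbered 3 and 0 to 23.2 CPM in those numbered 1. By a rule of over 5 CPM in the 5 embryos of 1 number and under 1 CPM in the other 10, or the reverse, WT number 3 alone had genes, 3 present (kirre, CG2812, GstE10) and 2 absent (Cyp4p2, Cyp12a4). The labels do not say what embryos of 1 number share.

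Of the tests below, those on depth, gene length, chromosome arms and stage were chosen before the results were seen, and the others only after. For gene counts, the libraries of each comparison were split in other ways. Of the 100 splits drawn, the real one alone gave as many genes in each of 6 comparisons. Chance can thus be excluded as the sole source of those counts. The real counts and the highest others were 504 and 257 (Slbp pre-NC9), 4539 and 3679 (Slbp NC13), 2429 and 1191 (difference between stages), 4274 and 3163 (WT NC13 against pre-NC9), 3141 and 2687 (WT NC14 against NC13), and 1387 and 518 (Slbp NC13 against WT NC14). The median of the others was 0 (2 in the last). The splits behind 257, 3679, 3163 and 2687 had at most 1 embryo per group misplaced. For abo from NC10 to NC14, embryos of 1 number were not independent, so whole numbers were exchanged, and the 10 splits of 3 against 3 numbers are too few for a share under 0.05. The real counts and highest others were 1561 and 639 for the average and 30 and 1 for differences between stages. Exchanged singly within stages, embryos gave at most 9 and 20 genes in other splits, which takes them as independent. The 10 splits of 3 against 3 libraries are also too few. Their real counts and highest others were 814 and 0 in the pools, 144 and 1 at NC10, 117 and 3 at NC11, 98 and 0 at NC12, 472 and 0 at NC13, and 352 and 5 at NC14.

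The rise of histone reads at Slbp NC13 was weighed first. Variant gene reads counted for the families are unlikely as the whole source if both genotypes misassign the same share. Summed, the 6 variant genes rose 1.316-fold and 4 families 18.27-fold. Over Slbp-WT library pairs no variant gene rose over 6.526-fold, and the family sum rose at least 12.92-fold. A small part and His2A alone (log2 2.14) stay open. Library scaling is unlikely, since the lowest log2 of the 4 families over all settings was 1.971. Whether the maternal Slbp level alone was the source stays open. All 5 families had a higher effect at NC13, where Slbp was less depleted, than at pre-NC9, but embryos at pre-NC9 precede zygotic transcription, so histone mRNA not yet made there could not show an effect. A candidate explanation that remains is more polyadenylated histone mRNA after defective 3' end processing, which libraries primed on poly(A) count and other histone mRNA would escape, and neither it nor a change in total histone mRNA was tested here.

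The stage score of Slbp NC13 embryos at the level of WT NC14 was weighed next. Sequencing depth is unlikely, since at equal depth the difference from WT NC13 was 1.959. Embryos wholly like WT NC14 embryos are unlikely as well, since the median of cellularization genes against WT NC14 was -0.2754. Long genes finished in a longer interphase may have a part. Gene span correlated with the Slbp effect at NC13 across 323 zygotic genes (Spearman 0.4155, interval over genes 0.322 to 0.501). The value for Slbp NC13 against WT NC14 was 0.196, and that at pre-NC9 0.112. The WT change from NC13 to NC14, against the same WT NC13 embryos, also followed span (0.359). A difference in age or in the number of cycles reached, with the stage read from nuclear density, stays open and was not tested.

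Genes called in the same direction at NC0 and in the NC10 to NC14 average of abo were weighed last (60 genes, 31 higher; of the 57 tested in pools, 14 were called the same way and 2 the opposite way). Their effects need not be equal at each stage, and Socs44A is 1 of them. Background linked to abo on arm 2L may explain some. On 2L lay 28.33% of them against 17.54% of tested genes (Fisher adjusted p = 0.0776 over the arms). Arm 2R of the same chromosome was as rich (31.7% against 20.3%), and 3R poorer (10% against 24.2%, adjusted p = 0.0555). A stage difference cannot be told, with a Spearman correlation of 0.2097 to the WT change, nor can presence in 1 strain alone, with 11.67% of them (7 genes) near absent in 1 genotype. Genes changed in Slbp embryos at both stages (301 genes, 237 higher) lay on arm 3R, which carries Slbp, at 21.59% against 24.0% of tested genes. This leaves a linked background open, since RNAi does not alter the Slbp locus and the place of the construct is not given in the sources used here.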
